A study of Drosophila melanogaster with 8 samples.

How the data were processed

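RNA from the heads of female Drosophila melanogaster was measured on 8 long-oligonucleotide microarrays, each with 2 colours. The flies carried a ubiquitous GeneSwitch driver and a hairpin directed at ATPsyn-d, the gene of subunit d of the mitochondrial ATP synthase (ATPsynD in current nomenclature). GeneSwitch is a form of the yeast activator GAL4 that is active when its ligand RU486 (mifepristone) is fed. Per the labels, 4 arrays came from 14-day-old flies fed 200 uM RU486 and 4 from flies without it, on a diet of 2% sugar and 18% yeast, and 3.5 ug of total RNA was labelled. The sample was labelled with Cy3 on every array and a common reference, described as from Canton S female heads, with Cy5. Dyes were therefore not swapped, and a dye bias of a probe is shared by both groups. Some log2 ratios without RU486 are hard to reconcile with a head reference. The photoreceptor gene rdgA (4.03) and the neuron gene Gad1 (3.04) stood far above it, and the midgut gene alphaTry (-5.77) far below. The tissue of the reference is therefore uncertain. The labels call the replicates biological, and no line fed RU486 without the hairpin was part of these samples, so an effect of the drug and an effect of the knockdown cannot be separated in this design.

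Per the file headers, the arrays were scanned at 532 nm (Cy3) and 635 nm (Cy5) and read with GenePix Pro 6.0.0.45. The deposited scanner tables give the foreground and local background intensity of each spot, without background subtraction, the percent of its pixels above background plus 2 SD and the percent saturated, and a flag score (0 unflagged, -50 not found, -75 absent, -100 bad). A deposited table for the whole series holds the authors' log2 ratio per spot. Set against the scanner values of bright spots, its columns correlated with log2(Cy3/Cy5) at r = 0.982 to 1.000 across spots, with slopes of 0.921 to 0.997, so the scale is log2 and the direction is sample over reference. Its column medians were 0.0593, 0.0506, 0.106 and 0.111 for the arrays without RU486 and 0.0675, 0.0680, 0.0696 and 0.0671 for those with it. The authors' exact normalization is not given in the sources used here. Every flagged spot was empty in that table, as were 995 to 1905 unflagged spots per array, and it was used only as an alternative.

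Each array held 16416 spots, of which 14480 carried a fly transcript name (14445 probes). Gene names came from the CG or CR number in the probe name, through a RefSeq table of Drosophila melanogaster (Release 6 plus ISO1 MT), which matched 13200 of 13820 numbers. The other 620 keep the name in the files, and no coordinates are given because the files name no genome build. The mean foreground and median background intensities were corrected with limma 3.58.1 in R 4.3.3 (normexp, offset 50) and normalized within arrays by loess, with control spots at weight 0 and none between arrays. Values are log2(Cy3/Cy5), spots flagged absent or bad were left out, spots flagged not found were kept as dim values, and spots of a probe were averaged. A probe was kept when at least 50% of its pixels exceeded background plus 2 SD in Cy3 on at least 4 of the 8 arrays, which left 8326 probes of 7804 genes. Groups were compared with lmFit and eBayes, RU486 minus no RU486, two-sided, with Benjamini-Hochberg adjustment over all kept probes and a threshold of 0.05. A gene is represented by its probe with the highest mean signal. Among genes with several probes, 2 had a probe past the threshold and probes in both directions.

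Before the data were examined, 30 gene lists, the tests, the alternatives and the rule for naming genes were fixed. Lists with at least 5 kept members (29 of them; the male accessory gland and testis list had 2) were tested with camera at its preset correlation of 0.01, adjusted over the 29 lists. Camera with an estimated correlation and fry stand beside it. Where the CG number of a list entry belonged to another gene, the symbol was followed for 4 entries and a synonym for 1. The entry Os9 was found by its number alone, which belongs to Cenp-C, a gene without a kept probe. Genes named in the text are ATPsyn-d, the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap (all 6 falls, as there were fewer), genes of smallest p added to reach 20, and up to 4 members of each list with the smallest p. The 2 genes so added, CG14132 and CG31706, were past the threshold too.

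Precision is limited by 4 arrays per group, and the median SE of a log2 change was 0.191. The steps were tested on simulated data with the means and spreads of these 8326 probes. Of probes changed by 1, 1.5 and 2 on the log2 scale, 67.5%, 94.6% and 100% were recovered, 2 of 8126 unchanged probes were called, and a list shifted by 0.4 was the 1 list called. Noise was drawn independently for each probe, so the list result does not cover genes that vary together. In the real lists the estimated correlation reached 0.495 (neuron). A further test multiplied or divided the background-subtracted Cy3 intensity of probes by 4 in the RU486 arrays of the deposited files. The added change of 2 came back as 1.87, 1.69 and 1.71 in dim, middle and bright probes, and the change of -2 as -1.42, -1.68 and -1.68. After background correction alone, the bright probes still held 1.96 and -1.86. The rest was lost in the loess step, because the fitted curve of log2(Cy3/Cy5) climbed with brightness by 0.0969 to 0.230 per log2 unit among bright probes, and a changed spot moves along it. In dim probes the offset of 50 took more from falls than from rises. Log2 changes given here are therefore compressed, falls of dim probes most.

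Scan times in the headers part the arrays into 2 sessions, each with 2 arrays of each group (replicates 1 and 2, then replicates 3 and 4). Session was tried as a block and each session was fitted alone. Further alternatives were no background correction, plain subtraction, median centring, print-tip loess, Aquantile (which leaves log ratios as they are) and scale normalization between arrays, Cy3 alone with quantile normalization, no filter and a stricter filter on dim probes, replicate number as a block, array weights, eBayes with trend and robust settings, a threshold of 0.10, each array left out, and the authors' log2 values. Chosen after the data were seen were the median foreground, leaving out spots flagged not found, leaving out the 2 dim arrays, and removing the trend of the change with brightness. In the comparison of settings, a gene or list past the threshold in neither setting counts as the same whatever its sign.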

Results

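Head RNA of females carrying an inducible hairpin against ATPsyn-d was compared between flies fed RU486, which switches the hairpin on, and flies without it, with 4 arrays per group. Brightness differed between arrays. The arrays without RU486 had a median Cy3 intensity above background of 555, 452, 220 and 267 for replicates 1 to 4, and those with RU486 had 515, 604, 636 and 577. The Cy5 reference was dim on the same 2 arrays, at 91 and 129 against at least 294 elsewhere. These arrays, replicates 3 and 4 without RU486, were scanned in session 2 together with replicates 3 and 4 with RU486. The Cy3 detector gain was 560 for these dim arrays and 550 for the RU486 arrays of session 2. Within that session gain and treatment cannot be told apart, while in session 1 the gain was 550 for both groups. In both sessions the arrays without RU486 were scanned before those with it. Scan order and treatment therefore cannot be told apart in either session. Across probes, arrays correlated at r = 0.927 to 0.966 within groups and 0.914 to 0.949 between groups. Arrays did not simply group by treatment. Replicates 1 and 2 without RU486 correlated at 0.927 to 0.935 with the 2 dim arrays of their own group. With RU486 replicate 1 they correlated at 0.949 and 0.946.

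**Figure D1:**
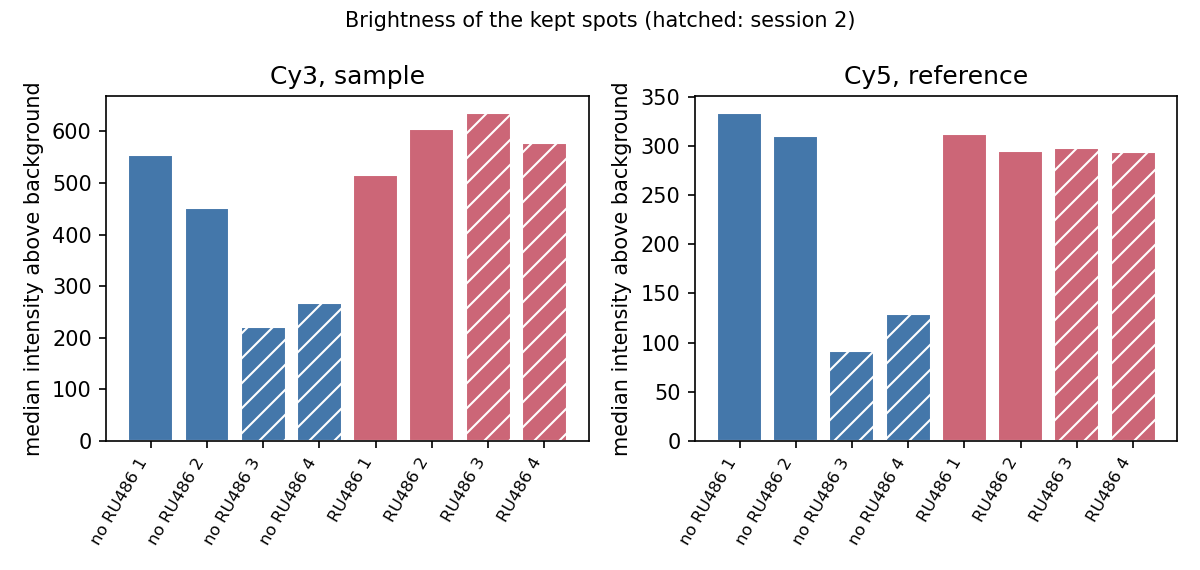
Median intensity above local background of the kept spots (scanner units), in Cy3 (sample) and Cy5 (reference), for each array. Bars are single arrays, blue without and red with RU486. Replicates 3 and 4 without RU486 stand lowest in both channels, at 220 and 267 in Cy3.

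The targeted transcript, ATPsyn-d (CG6030, 1 probe), checks whether the knockdown is visible in whole heads. Its log2 ratio to the reference was 0.22 ± 0.17 (SD, n = 4) without RU486 and 0.04 ± 0.17 (SD, n = 4) with it. The difference was -0.18 (SE 0.155), a fold of 0.884 with a 95% interval of 0.698 to 1.12, which holds both no change and a modest fall. This difference was not told apart from 0 (exact two-sided permutation p = 0.2, limma adjusted p = 0.711). It was -0.14 in session 1 and -0.22 in session 2. Among the other measured subunits of the ATP synthase, 4 were higher and 7 lower. Of 11 measured members of that list 0 passed the threshold, with ATPsynC at -0.26 and ATPsynB at -0.19, and the list as a whole was not called (camera adjusted p = 0.304).

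Which transcripts differed with RU486 was asked of all 8326 probes. The white gene (w, CG2759), which encodes an ABC transporter of eye pigment precursors, rose 21.9-fold (log2 4.45, SE 0.198, limma adjusted p = 1.31e-06), from 0.31 ± 0.28 to 4.77 ± 0.30 (SD, n = 4 each). It was above background on 2 of the 4 arrays without RU486 and on all 4 with it. Mtk (CG8175), which encodes the antimicrobial peptide metchnikowin, had the largest fall among genes past the threshold, by 3.49 on the log2 scale (SE 0.365, limma adjusted p = 0.00252), to a fold of 0.0893. CG2444 rose 8.62-fold (log2 3.11, SE 0.284, adjusted p = 0.00129 in limma) and was above background on 1 of 4 arrays without RU486. In all, 61 probes of as many genes passed the threshold, 54 higher and 7 lower. Judged by each gene's probe of highest mean signal, 52 genes passed (46 higher, 6 lower). In the others a dimmer probe passed and the brightest did not, as for trio (1.70 against 0.34) and Fife (1.335 against 0.16). Tested in each session separately, 11 probes passed the threshold in both, in the same direction. The sizes depend on the setting, which includes the processing and the arrays used: over those tried w ran from 3.82 to 5.16 and CG2444 from 2.65 without background correction to 4.41 with plain subtraction, and the fold of 16 of 20 named genes moved by over 1.5 times in at least 1 setting.

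**Figure D2:**
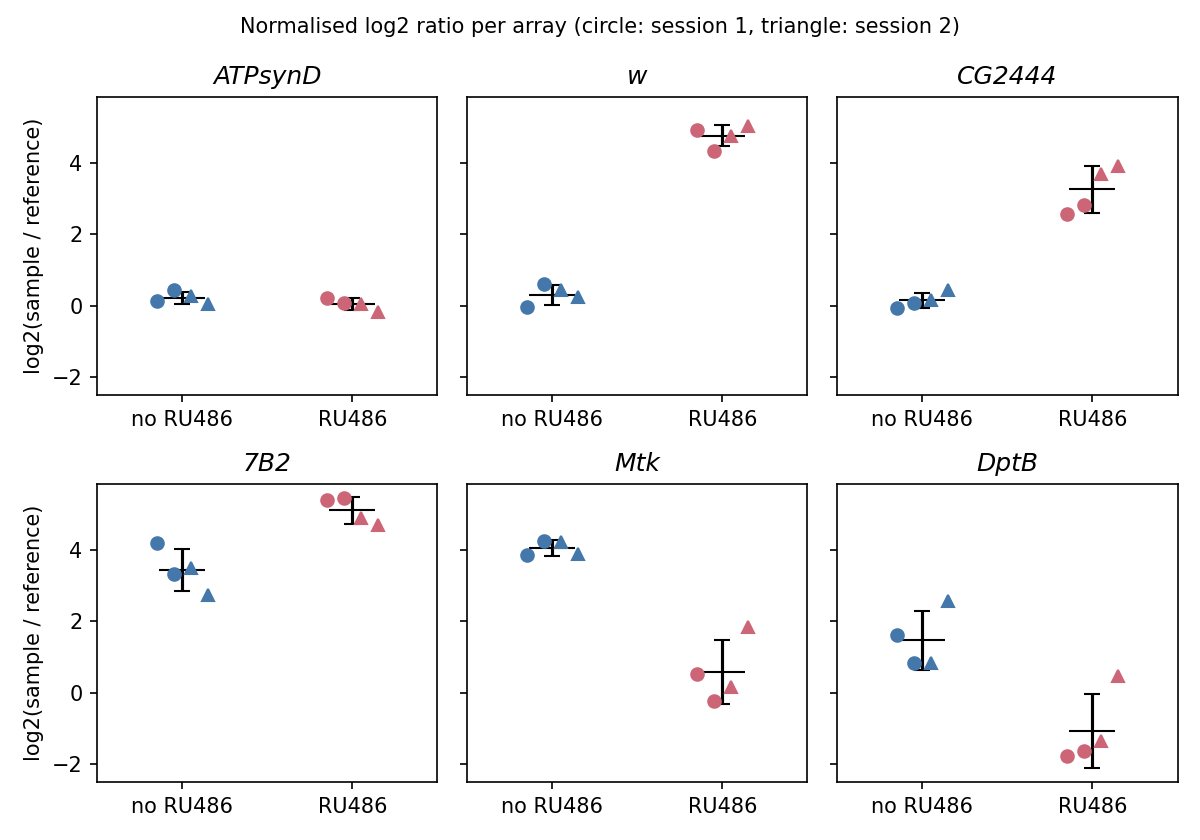
Normalized log2 ratio of sample to reference for 6 genes on each array. Points are single arrays, circles for session 1 and triangles for session 2, and black bars are the mean and SD of 4 arrays. For w the arrays with RU486 lie between 4.35 and 5.03 and those without between -0.03 and 0.62, while those of ATPsynD overlap.

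Other large rises reached genes of several kinds. 7B2, whose product helps mature the prohormone convertase that cuts neuropeptide precursors, rose by 1.67 (SE 0.289). Syt7, which encodes a synaptotagmin, rose by 1.51, and Spn47C, which encodes a serpin, rose 2.82-fold. NtR stood at 1.51, and the genes named only by number were CG4409 at 1.76, CG33203 at 1.63, CG3257 at 1.62, CG7135 at 1.59, CG40306 at 1.55, CG14132 at 1.43 and CG31706 at 1.20. Ste:CG33245, at 1.89, is a copy of the repeated Stellate genes, and its value is uncertain because near-identical copies share sequence. Besides Mtk, the falls were CG8665 (-1.63), Rpp14b (-1.29), BomS3 (-1.14, saturated on 1 array), prd (-1.12) and TTLL1A (-0.87). Spn47C was above background on 2 of 4 arrays without RU486, and CG8665 and TTLL1A on 2 and 1 of 4 arrays with it. Under plain background subtraction CG3257 turned to -0.22. The limma adjusted p of these rises and falls, Mtk apart, lay between 0.00379 and 0.0478. By the rule that named them, their groups do not overlap. Of all kept probes 7.72% had groups that did not overlap, where chance gives 2.86%.

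The number of changed probes depended on which arrays were used. With session as a block 61 probes passed, of which 50 were among the 61 of the main fit. Within session 1 there were 30 (19 higher, 11 lower) and within session 2 there were 498 (443 higher, 55 lower), and 37 probes passed a test of the difference between sessions. Without the 2 dim arrays 43 passed (33 higher, 10 lower), without RU486 replicate 2 or 3 only 5 did, without RU486 replicate 4 there were 15, and leaving out replicate 3 of the group lacking RU486 gave 24.

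Genes of the antimicrobial and immune list were lower with RU486. Of 37 measured members 26 were lower and 11 higher, and the list median was -0.27 (camera adjusted p = 3.28e-05, and adjusted p = 0.344 with an estimated correlation). Over all probes 2 members fell, Mtk and BomS3, and adjusted over the list alone 6 fell and 2 rose. DptB, which encodes a diptericin, was at -2.54 (SE 0.512, limma adjusted p = 0.0541) and was above background on 1 of 4 arrays with RU486. PGRP-LC, a receptor for bacterial peptidoglycan, was at 0.78 (SE 0.194, limma adjusted p = 0.0956). Within sessions the list median was -0.68 in session 1 and -0.10 in session 2. Markers of fat body, a source of antimicrobial peptides, were lower as well (below).

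Markers of eye and blood cells were higher. The photoreceptor list had a median of 0.39 (camera adjusted p = 0.00146, adjusted p = 0.495 with an estimated correlation). Of its members 1 rose over all probes, ninaB, a carotenoid oxygenase needed to make the visual chromophore, by 1.42 (above background on 2 of 4 arrays without RU486), and 5 rose adjusted over the list alone, with ninaA at 1.16 and rdgA at 1.21. The list turned to -0.11 with scale normalization, was at -0.08 within session 1 and 0.88 within session 2, and the dim arrays lacking RU486 all belong to session 2. The hemocyte list had a median of 0.44 (camera adjusted p = 0.0253, adjusted p = 0.392 with an estimated correlation). Of its 12 members 0 passed over all probes, while 6 rose and 1 fell adjusted over the list alone, among them PPO2 at 0.91 and eater at 0.80. Its median was 0.31 in session 1 and 0.91 in session 2. Neuron (median 0.13), glia (0.21), muscle (0.08) and chemosensory (0.08) markers were not called as lists. In sessions 1 and 2 their medians were -0.25 and 0.75 for neuron, -0.27 and 0.51 for glia, 0.01 and 0.21 for muscle and -0.02 and 0.20 for chemosensory genes. Yet bt, which encodes a giant muscle protein, rose by 0.82.

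Markers of fat body, ovary and gut were lower as lists, with 0 members past the threshold over all probes or adjusted over the list alone. Several midgut and egg chamber genes stood far below the reference without RU486 (alphaTry at -5.77, Cp19 at -4.38), though Cp7Fa stood at 0.50. Some were dim, with nanos above background on 1 of 4 arrays without RU486. These shifts therefore do not show a loss of ovary or gut RNA. Yolk and fat body genes had a median of -0.38 (camera adjusted p = 0.0202, adjusted p = 0.229 with an estimated correlation), and the yolk protein genes Yp2 and Yp3 are given no size here, since most pixels of their spots were saturated in Cy3 on 5 and 2 of the 8 arrays. Egg chamber genes had -0.33 (camera adjusted p = 0.00167, adjusted p = 0.344 with an estimated correlation), with the chorion gene Cp18 at -0.79. Midgut proteases had -0.37 (camera adjusted p = 0.00119, adjusted p = 0.344 with an estimated correlation), with Jon65Aiv at -0.54. Scale normalization turned the egg chamber list to 0.36 and the midgut list to 0.35. That setting evens out the spread of log ratios, which was narrowest on the 2 dim arrays (SD 1.17 and 1.28). In session 1 these 3 medians were -0.13, -0.19 and -0.05, and in session 2 they were -0.39, -0.28 and -0.63.

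Lists of metabolism and protein turnover moved little. Cytosolic ribosomal proteins had a median of -0.16, with 72 of 82 members lower and 0 past the threshold (camera adjusted p = 1.56e-09, adjusted p = 0.229 with an estimated correlation). These are among the brightest probes, and the median change of all probes ran from 0.14 in the dimmest decile to -0.11 in the brightest; with that trend removed the list stood at 0.01. Proteasome genes had -0.14 (camera adjusted p = 0.00119, adjusted p = 0.146 with an estimated correlation), with 27 of 32 lower and 0 past the threshold. Lipid metabolism had -0.19 (camera adjusted p = 0.0206, adjusted p = 0.495 with an estimated correlation), and the acyl-CoA dehydrogenase gene Mcad, at -0.65, fell adjusted over the list alone. With Cy3 alone the medians of the proteasome and lipid lists were 0.12 and 0.10. The TCA cycle list had -0.10 (camera adjusted p = 0.0287, adjusted p = 0.229 with an estimated correlation), with the malic enzyme gene Men at -0.73. In sessions 1 and 2 the medians were -0.14 and -0.22 for ribosomal, -0.08 and -0.06 for proteasome, -0.26 and -0.02 for lipid and -0.08 and -0.10 for TCA cycle genes.

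The remaining lists were not called. Respiratory complex I had a median of 0.03 (camera adjusted p = 0.555) and complexes II to IV -0.02 (camera adjusted p = 0.222), with 0 members past the threshold in either. TOR and insulin signalling, part of the question in the study's title, had -0.01 (camera adjusted p = 0.394), with AMPKalpha at 0.59 and Thor, which encodes the translation repressor 4E-BP, at -0.47, both not past the threshold. Heat shock and chaperone genes had -0.02, autophagy -0.11, mitochondrial quality control -0.08, glycolysis 0.01, mitochondrial ribosomal proteins 0.01, carbohydrate digestion -0.14, the circadian clock 0.24 (-0.14 in session 1, 0.39 in session 2) and juvenile hormone and ecdysone genes 0.13. Antioxidant genes had -0.06, with Zw, which encodes glucose-6-phosphate dehydrogenase, rising by 0.83 and MtnB, a metallothionein gene, at -1.18. Cytochrome P450 genes had 0.17, with 2 members rising adjusted over the list alone (Cyp305a1 at 1.03 and Cyp12a5 at 1.01), and glutathione and UDP transferases -0.06, with GstZ2 at 0.99.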

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

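Of 163 groups of 4 arrays examined, 3 held an array far from the others, fewer than the 8.15 that chance would give. Zw was at 0.59 on replicate 3 without RU486, against 0.89 to 0.95 on the others. Cyp12a5 was at 0.13 on replicate 1 without RU486, against 0.75 to 0.85, and Lon at -0.37 on replicate 4 without RU486, against 0.38 to 0.43.

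In the weighing that follows, the tests of white, of the trend with brightness on the probe counts, of the offset and of tissue shares were chosen after their values had been seen.

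The excess of rises (54 of 61 probes) was weighed first. For the count of 61, 1 of 35 splits of the arrays gave as many, the real one, and the highest other gave 2. This argues against chance for the count, but 35 splits are too few to exclude it. The splits ignore the scan sessions, and they test the number of calls, not the excess of rises. A trend with brightness alone does not account for it, because 29 probes were still higher and 6 lower once the trend was removed. The dim arrays lacking RU486 stay open: the 443 probes called higher in session 2 had a median change of 0.057 in session 1 (95% bootstrap interval 0.0027 to 0.131), on both sides of the bound of 0.1 set beforehand. The bootstrap drew probes, so its interval holds no spread between arrays. Log ratios were also narrower on the 2 dim arrays (SD 1.17 and 1.28) than on the others (1.411 to 1.495). Narrower ratios there can make genes above the reference look raised with RU486 and genes below it look lowered. At an unadjusted p under 0.05, with 751 probes higher and 303 lower at first, session 1 alone held 449 and 442, leaving out the dim arrays gave 571 and 481, scale normalization 513 and 536 and plain subtraction 430 and 327. Other settings kept the excess. No background correction gave 803 and 291, median centring 928 and 151, print-tip loess 705 and 313 and the authors' values 737 and 321. Leaving out only replicate 3 or only replicate 4 without RU486 gave 590 and 275 or 633 and 271. Most rises seen only in session 2 may therefore come from the dim arrays. The 19 probes called higher in session 1 had a median of 1.03 in session 2, where the dim arrays may enlarge rises. The 11 called lower had -0.79 there (95% bootstrap interval over probes -2.02 to 0.45). Compression of falls by the background offset stays open. Calls were 38 higher and 5 lower in the dimmest tercile of brightness, 16 and 0 in the middle and 0 and 2 in the brightest. No setting changed the offset alone.

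White was weighed next. A mislabelled array is argued against by the gap of 3.73 between the groups, and the dim arrays by a change of 4.34 in session 1 alone. A joint rise of eye pigment genes as large as that of white is argued against by st and bw, whose highest probe reached 0.82. A smaller one stays open. The other measured pigment genes, looked up after the results were seen, were higher too but not past the threshold. Of these, st was at -0.26 in session 2 and ry at -0.10 in session 1. All of them stood above the reference without RU486, where the narrower ratios of the dim arrays can also raise a gene. A candidate explanation is a white marker gene on a transgene, read when the driver is active, but the 1 vector probe above background on all arrays is not known to belong to this transgene, so it cannot be told apart from a response of the gene itself to RU486.

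The list shifts came last. Chance is not excluded for the count of 10 lists, as 3 of 35 splits gave as many, with 15 the highest other. Both other splits kept the 2 dim arrays together, and the split by scan session called 4 lists and 2 probes. Against 10000 random lists matched on brightness, the medians lay at percentile 0 for antimicrobial, yolk and egg chamber genes, 0.01 for midgut, 0.14 for lipid, 0.48 for proteasome, 99.99 for hemocyte and 100 for photoreceptor genes, but the trend may account for TCA cycle (23.8) and ribosomal genes (13.3). In session 1 alone, free of the dim arrays, the antimicrobial (0), lipid (0.19), ribosomal (1.04) and hemocyte (99.86) lists lay outside the central 95% of such lists, while TCA cycle (42.5), proteasome (32.1), yolk (16.56), egg chamber (6.72), midgut (47.6) and photoreceptor (27.6) did not, so the dim arrays may account for these 6. A change in tissue shares stays open: the medians of the hemocyte and muscle lists differed by 0.36, with a 95% bootstrap interval of -0.11 to 0.82. That bootstrap drew genes, so its interval holds no spread between arrays. The random lists drew genes independently, so their percentiles take no account of genes that vary together or of the spread between arrays. Members of the antimicrobial list had an estimated correlation of 0.166, and session 1 holds 2 arrays per group, scanned in the order of treatment. For the antimicrobial list the percentiles of 0 therefore argue against the trend and the dim arrays as the only source, but exclude neither. Fat body makes many of these peptides and the yolk and fat body list was lower too (-0.38), so a smaller share of that tissue was not excluded, and a response to RU486 or to the hairpin is a hypothesis that this design leaves untested.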

How the results depend on the processing

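The ATPsyn-d probe was past the threshold in no setting, and Mtk was past it in all 27 settings counted, w in the 26 and CG2444 in the 25 that gave them a value, but 37 of the 61 probes were past it in fewer than 50% of them, among them 7B2 (11), NtR (9), ninaB (8), amon, Eaat2 and bt (7 each), CG33203 and Gpb5 (6 each), Zw (5) and TTLL1A (4). The median foreground, dim arrays left out, not-found spots left out and the trend removal were chosen after the data were seen. Aquantile leaves the ratios as they are and tests nothing, and dim signal (46.7% of probes above background on the dimmest array) limits the smaller changes. In session 2 the probes above background were 46.7% and 49.5% without RU486 against 63.6% and 61.7% with it. The filter could therefore admit more probes through the RU486 arrays. Without it 914 probes were higher and 627 lower at an unadjusted p under 0.05, against 751 and 303 with it. The cause of the shifts that follow was not tested, except that single sessions and left-out arrays use fewer samples.

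Probes changed numbered 5 (3 higher, 2 lower) with plain subtraction, 100 (92 higher) with median centring, 38 (30 higher) with print-tip loess, 8 (4 higher, 4 lower) with scale normalization, 9 (3 higher) with Cy3 alone, 40 (29 higher, 11 lower) without a filter, 37 (34 higher, 3 lower) with the stricter filter, 20 (15 higher) with trend and robust eBayes, 182 (158 higher, 24 lower) at 0.10, 11 (8 higher, 3 lower) with the median foreground, 43 (33 higher) without the dim arrays and 35 (29 higher) with the trend removed. Without background correction 4 were lower. Higher calls were 88.5% of the total at first, 94.7% without background correction, 92% with median centring, 91.5% with the authors' values, 79.0% with print-tip loess, 60% with plain subtraction, 50% with scale normalization and 33.3% with Cy3 alone. Sessions 1 and 2 alone gave 30 (19 higher, 11 lower) and 498 (443 higher, 55 lower). The replicate block gave 13 (11 higher, 2 lower); same-numbered arrays deviated from their group means with correlations of -0.038 to 0.048, so the numbers do not pair the arrays. Leaving out each array gave 5 to 67 probes, 4 to 62 higher and 1 to 6 lower.

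Lists changed numbered 10, and 6 with plain subtraction, 2 with Cy3 alone, 1 in session 1, 0 with an estimated correlation, 3 with fry, 3 without the dim arrays and 5 with the trend removed. Scale normalization reversed egg chamber (0.36), midgut (0.35), photoreceptor (-0.11), neuron (-0.19) and chemosensory genes (-0.32), Cy3 alone reversed lipid (0.10) and proteasome genes (0.12), and plain subtraction reversed CG3257 (-0.22). Over the 27 settings, the 23 named genes past the threshold lost the call in 250 of 609 comparisons, and the 110 others gained it in 45 of 2941.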

Other observations

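The genes in this part were looked up after the results were seen. Of 28 measured genes of the antimicrobial peptide families, taken by symbol after a smaller choice by hand, 24 were lower with RU486 and 4 higher, and 18 were lower in both sessions, although only Mtk and BomS3 passed the threshold. Drsl1 was at -3.54, Drs at -3.09, AttA at -1.58, DptA at -1.52 and AttC at -1.09, with limma adjusted p of 0.0874, 0.143, 0.305, 0.274 and 0.109. In session 1 Drs was at -4.49 and in session 2 at -1.70. Attacin and Bomanin genes have close copies whose probes can share signal, so these 28 genes are not independent of each other.

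Genes of neuropeptide maturation included amon, the convertase that 7B2 assists, which rose by 1.40 (limma adjusted p = 0.0463), at 1.25 in session 1 and 1.55 in session 2. A probe of Pal2, which encodes an enzyme of peptide amidation, rose by 1.63 while its brighter probe stood at 0.40, and Phm and Pal1 stood at 0.11 and 0.20, not past the threshold. Also past the threshold were Gpb5, a glycoprotein hormone subunit, at 1.34, Eaat2, an amino acid transporter, at 0.95, and Rbp6 at 1.30. For trio the called probe was at 1.70 and the brighter probe at 0.34. Counting w, all 6 measured eye pigment genes were higher, 4 of them in both sessions. Besides w these were v at 0.82, se at 0.71, st at 0.63 (1.53 in session 1, -0.26 in session 2), bw at 0.44 and ry at 0.40 (-0.10 in session 1, 0.90 in session 2), all not past the threshold.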
